A study of Burkholderia multivorans with 3 samples.

How the data were processed

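RNA was sequenced from the rhizosphere bacterium Burkholderia multivorans WS-FJ9, a strain that releases phosphate from insoluble minerals. The bacteria had been grown with 0, 5 or 20 mM soluble phosphate, and each level was represented by 1 library. Per the labels' protocols, RNA was isolated with Trizol and libraries were made with an Illumina TruSeq RNA kit by a strand-specific protocol. Whether ribosomal RNA was removed is not given in the sources used here.

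The authors deposited 1 table per library, with the same 2047 contig identifiers in each. Per the file headers, the values are RPKM, that is, reads scaled to the length of the contig and to the total reads of the library by the authors. The submitters' processing notes name Cuffdiff, without a version or a role. The assembler, aligner and reference are not given in the sources used here. The identifiers have the form of contigs from a transcript assembly over the libraries together: 1370 are numbered singly (Unigene) and 677 belong to 241 numbered clusters (CL). Members of a cluster are taken here to be related sequences, so reads may have been divided between them. The files pair the identifiers with neither gene names nor sequences, and no annotation was used here. The 16 gene lists fixed before the data were examined (phosphate starvation, glucose oxidation, ribosomal proteins and others) therefore matched 0 identifiers. The list medians and the comparison with 10000 random lists could not be made. Each comparison below is of contigs, not of named genes.

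The RPKM values still carry whole reads. Contigs with equal reads in 2 libraries share 1 ratio of RPKM, which is the ratio of the library totals, and low contigs give the totals themselves. The total at 0 mM was sought among whole numbers and came to 6104467 reads. Of the 159 contigs used to find it, 78.6% had a whole length at that total. With the ratios, the other totals came out within 0.0004 of the whole numbers 6499925 at 5 mM and 5983296 at 20 mM. The smallest contig length up to 150000 nt that made the reads whole in all 3 libraries, within the rounding of the files (10 significant digits, at most 9 decimals), was then found for each of the 2047 contigs. Such a length and its reads are minimum values: where all 4 numbers share a divisor, it cannot be seen. The recovered reads came to 96.2% of the total at 0 mM, 96.2% at 5 mM and 96.1% at 20 mM. On simulated libraries of 2036 contigs for 5 mM against 0 mM, all 3 totals were recovered exactly and 93.5% of contigs came out with their simulated length and reads. The remaining contigs came out at a whole divisor, and 97.2% of the simulated reads were recovered. A hidden divisor is possible at any length, so the length classes below rest on minimum lengths. The lengths of 93 contigs came out under 150 nt.

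The difference between 2 libraries was log2(RPKM + 1) at the first level minus that at the second, on the deposited values with no further scaling. A fold change on this scale understates the change of low contigs. With 1 library per level there is no spread between replicates, so no test was run and no p-value is given for any difference between phosphate levels. A contig was called higher or lower by a size rule set before the data were examined: at least 10 RPKM in 1 or both of the libraries and a difference of at least 1, that is 2-fold. In the same simulation, which had counting error only, all 75 of the 4-fold and all 73 of the 8-fold changed contigs above the minimum passed the rule in the right direction. Of 1282 unchanged contigs, 7 passed it by chance.

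Recovered reads were used for precision. Ratios of named contigs carry a 95% exact (Clopper-Pearson) interval of the 2 read counts, scaled by the library totals. A contig without reads was set to the limit that a count of 0 allows, 3 reads per library, which is 0.491 RPKM at 0 mM, 0.462 at 5 mM and 0.501 at 20 mM for a contig of 1000 nt. A fold bound from such a limit takes the other count as exact, so it is less cautious than an interval. Intervals and limits cover counting error only, since reads are not independent molecules and cultures were not replicated. The contigs named in the text are the 2 with the largest and the 2 with the smallest difference per comparison among those past the rule, as set beforehand for identifiers without names.

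Alternatives set beforehand were a pseudocount of 0.1 or 10, no minimum or one of 50 RPKM, a 4-fold threshold, centring on the median difference, upper quartile scaling, equal totals, and the 10 most abundant contigs left out with equal totals. Upper quartiles were taken over each library's own contigs with reads. Equal totals means an equal sum of RPKM over contigs, and the 10 most abundant contigs here are those of highest mean RPKM. Setting contigs missing from a file to 0 was also planned and moved nothing, because no contig was missing. Summing clusters, keeping contigs of at least 1000 nt, keeping contigs with reads in all 3 libraries, and requiring a counting interval that excludes equality were chosen after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Growth and phosphate release at other phosphate levels, which the study's design also covers, were not analysed here.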

Results

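The transcriptome of Burkholderia multivorans WS-FJ9 was profiled at 0, 5 and 20 mM soluble phosphate, with 1 library per level, to learn how expression in a phosphate-solubilizing bacterium varies with the phosphate already in solution. The library totals were 6104467 reads at 0 mM, 6499925 reads at 5 mM and 5983296 reads at 20 mM. The 2047 contigs had a median length of 2247 nt, with quartiles of 344 and 6744 nt and a longest contig of 71553 nt. There were 305 contigs of at least 10000 nt, and the summed length was 9.81 Mb. A contig of this length spans many bacterial genes, so its RPKM is an average over neighbouring genes and a change in 1 of them is diluted. In the other direction, 620 contigs were under 500 nt. Because no level was replicated, every difference below is between 2 libraries, and the spread between cultures is unknown.

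The 3 libraries shared most of their abundant transcripts. Of the 10 contigs with the most reads in each library, 8 were common to all 3. Together the 3 lists named 14 contigs, of which 4 passed the 2-fold rule in at least 1 comparison. The 10 leading contigs held 24.3% of the recovered reads at 0 mM, 25.1% at 5 mM and 23.3% at 20 mM. Across contigs, the 5 and 20 mM libraries resembled each other most (Spearman's rho 0.98), and the 0 mM library correlated less with the 5 mM library (0.94) and the 20 mM library (0.93). Contigs are not independent replicates, so no p-value is attached to these values. The median RPKM over all contigs was 26.4 at 0 mM, 16.3 at 5 mM and 19.8 at 20 mM. Reads were found on 2009 contigs at 0 mM, 1725 at 5 mM and 1743 at 20 mM.

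Between 5 mM and 0 mM phosphate, most contigs that differed were lower with phosphate. Of the 1409 contigs with at least 10 RPKM in 1 or both libraries, 248 were at least 2-fold lower at 5 mM and 36 at least 2-fold higher, together 20.2%. At least 4-fold differences were seen for 29 lower and 4 higher contigs. By the higher of the 2 values, 121 of the 466 contigs at 10 to 30 RPKM were lower, 113 of the 644 at 30 to 100 RPKM and 14 of the 299 that reached 100 RPKM. In this last group 17 were higher. The 36 higher contigs held 6.84% of the recovered reads at 5 mM against 2.28% at 0 mM, and the 248 lower contigs held 1.96% against 4.84%.

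Named contigs are ranked on the log2(RPKM + 1) scale, and the ratio of RPKM alone can rank others higher. The contig with the largest gain at 5 mM on that scale, CL36.Contig3_All (183 nt), had 16.8 RPKM at 5 mM and 0.895 RPKM at 0 mM. This rested on 20 reads against 1 read, an 18.8-fold ratio with a 95% exact counting interval of 3.0 to 779. CL128.Contig2_All (156 nt) had 21.7 RPKM at 5 mM and 2.10 RPKM at 0 mM, from 22 reads against 2, a 10.3-fold ratio with an interval of 2.54 to 90.6. Unigene1104_All (344 nt) had 22.4 RPKM at 0 mM, from 47 reads, and no reads at 5 mM. With the 47 reads taken as exact, it was at least 16.7-fold lower. It is one of 268 contigs with reads at 0 mM alone, for which RNA or DNA of another source cannot be told apart from transcription by the strain. CL228.Contig3_All (202 nt) had 20.3 RPKM at 0 mM, from 25 reads, and no reads at 5 mM. With the 25 reads taken as exact, it was at least 8.87-fold lower. The interval excluded equality for 246 of the 248 lower and 35 of the 36 higher contigs. It excluded a difference under 2-fold, the size of a call, for 131 of the lower and 24 of the higher contigs, so counting error alone leaves the size of many calls open.

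By length, of 230 contigs under 500 nt, 67 were lower and 16 higher at 5 mM. Of 286 contigs of 500 to under 2000 nt, 78 were lower and 4 higher. Of 893 contigs of at least 2000 nt, 103 were lower and 16 higher. Of clustered contigs 83 of 448 were lower (18.5%), and of singly numbered contigs 165 of 961 (17.2%). The median difference of all contigs above the minimum was -0.35 on the log2 scale, a 0.782-fold level. Relative to that median, 114 contigs were lower and 76 higher, so the share of higher contigs went from 12.7% to 40%. With libraries scaled instead to a common upper quartile of their own contigs with reads, 303 were lower and 30 higher, a share of 9.01%. These sets differ, with 2009 contigs at 0 mM and 1725 at 5 mM. Over all 2047 contigs the upper quartile was 51.3 RPKM at 0 mM and 44.8 at 5 mM, and that scaling was not run.

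Between 20 mM and 0 mM, lower contigs again outnumbered higher ones, by a smaller margin. Of 1415 contigs above the minimum, 161 were at least 2-fold lower at 20 mM and 59 at least 2-fold higher, together 15.5%. At least 4-fold differences were seen for 30 lower and 7 higher contigs. Among the 322 contigs that reached 100 RPKM the balance was the opposite, with 38 higher and 24 lower. The 59 higher contigs held 9.82% of the recovered reads at 20 mM against 3.16% at 0 mM, and the 161 lower contigs held 2.79% against 8.07%. The counting interval excluded equality for 160 of the lower and 58 of the higher contigs, and a difference under 2-fold for 92 of the lower and 43 of the higher ones.

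The 2 largest gains at 20 mM on the log2(RPKM + 1) scale were on well covered contigs. CL108.Contig2_All, a 20229 nt contig, rested on 43333 reads at 20 mM and 4865 reads at 0 mM. Its level was 358 RPKM against 39.4 RPKM, a 9.09-fold ratio with an interval of 8.82 to 9.36, and it had 82.3 RPKM at 5 mM. Of the same cluster, CL108.Contig1_All had 39.1, 19.4 and 36.3 RPKM at 0, 5 and 20 mM. CL108.Contig3_All had 32.2, 14.3 and 25.3 RPKM. A division of reads between these contigs was not tested. Unigene372_All (1686 nt) had 588 RPKM at 20 mM, 138 RPKM at 5 mM and 67.5 RPKM at 0 mM. Its ratio of 20 mM to 0 mM was 8.71, with an interval of 8.05 to 9.44. CL108.Contig2_All and Unigene372_All therefore had a higher value at each step of phosphate. The largest losses on that scale were Unigene1104_All, again without reads at 20 mM, and Unigene1100_All (841 nt). With its reads at 0 mM taken as exact, Unigene1104_All was at least 15.4-fold lower at 20 mM than at 0 mM. Unigene1100_All had 89 reads and 17.3 RPKM at 0 mM and no reads at 20 mM. With the 89 reads taken as exact, it was at least 29.1-fold lower. It had 2 reads at 5 mM. Its number lies between Unigene 1000 and 1400, a range in which 244 of 356 contigs had reads at 0 mM alone. For it, too, RNA or DNA of another source cannot be told apart from transcription by the strain.

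By length, 51 of 233 contigs under 500 nt were lower at 20 mM than at 0 mM and 20 were higher. Of 896 contigs of at least 2000 nt, 62 were lower and 30 higher. The median difference above the minimum was -0.18 on the log2 scale. Relative to it, 117 contigs were lower and 78 higher, and the share of higher contigs went from 26.8% to 40%. Upper quartile scaling over each library's own contigs with reads moved the share the other way, to 13.3%, with 255 contigs lower and 39 higher. Over all 2047 contigs the upper quartiles were nearly equal, 51.3 RPKM at 0 mM and 50.9 at 20 mM. This shift therefore rests on which contigs set the quartile.

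The libraries at 20 mM and 5 mM differed least. Of 1331 contigs above the minimum, 44 were at least 2-fold higher at 20 mM and 37 at least 2-fold lower, together 6.09%. At least 4-fold differences were seen for 7 contigs in each direction. The 37 lower contigs included many abundant ones: 25 reached 100 RPKM, and together they held 9.70% of the recovered reads at 5 mM against 3.22% at 20 mM. The 44 higher contigs held 6.76% at 20 mM against 2.64% at 5 mM. The interval excluded equality for 43 of the higher and 35 of the lower contigs, and a difference under 2-fold for 21 of the higher and 24 of the lower ones. The median difference was 0.25 on the log2 scale, and relative to it 23 contigs were higher and 57 lower. Upper quartile scaling gave 27 higher and 51 lower, equal totals 40 and 43, and equal totals with the 10 most abundant contigs left out 39 and 44. Each of these scalings shifts the contigs of a library alike, so they show only that the balance depends on the scaling. With the deposited scaling, 22 were higher and 24 lower with a pseudocount of 10, 22 and 29 with a minimum of 50 RPKM, and 22 and 26 over contigs of at least 1000 nt, chosen after the data had been seen. Higher contigs stayed in the majority without a minimum (90 against 66) and with a pseudocount of 0.1 (46 against 41). Of alternatives chosen later, they also did with clusters summed (30 against 25) and where the interval excluded equality (43 against 35). Which direction predominates between 20 and 5 mM is therefore not settled.

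On the log2(RPKM + 1) scale, the strongest loss between 5 and 20 mM was that of Unigene330_All (2513 nt), among the most abundant contigs at 5 mM. It had 2167 RPKM at 5 mM, 446 RPKM at 0 mM and 215 RPKM at 20 mM, from 35393, 6839 and 3233 reads. It was 10.1-fold lower at 20 mM than at 5 mM, with an interval of 9.72 to 10.4. Unigene754_All (5548 nt) had 863 RPKM at 0 mM, 701 RPKM at 5 mM and 72.6 RPKM at 20 mM, and was 9.65-fold lower at 20 mM than at 5 mM, with an interval of 9.26 to 10.1. On that scale the gains were led by CL5.Contig4_All (4271 nt), with 38.9 RPKM at 20 mM, 3.57 RPKM at 5 mM and 11.7 RPKM at 0 mM. It was 10.9-fold higher at 20 mM than at 5 mM, with an interval of 8.86 to 13.5. CL44.Contig1_All (1643 nt) had 129 RPKM at 0 mM, 14.6 RPKM at 5 mM and 109 RPKM at 20 mM, and was 7.48-fold higher at 20 mM than at 5 mM, with an interval of 6.32 to 8.90. For this contig the 5 mM library was the one that stood apart. Another contig of its cluster, CL44.Contig3_All, had 127 RPKM at 0 mM, 278 RPKM at 5 mM and 326 RPKM at 20 mM. A division of reads between them was not tested.

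**Figure D1:**
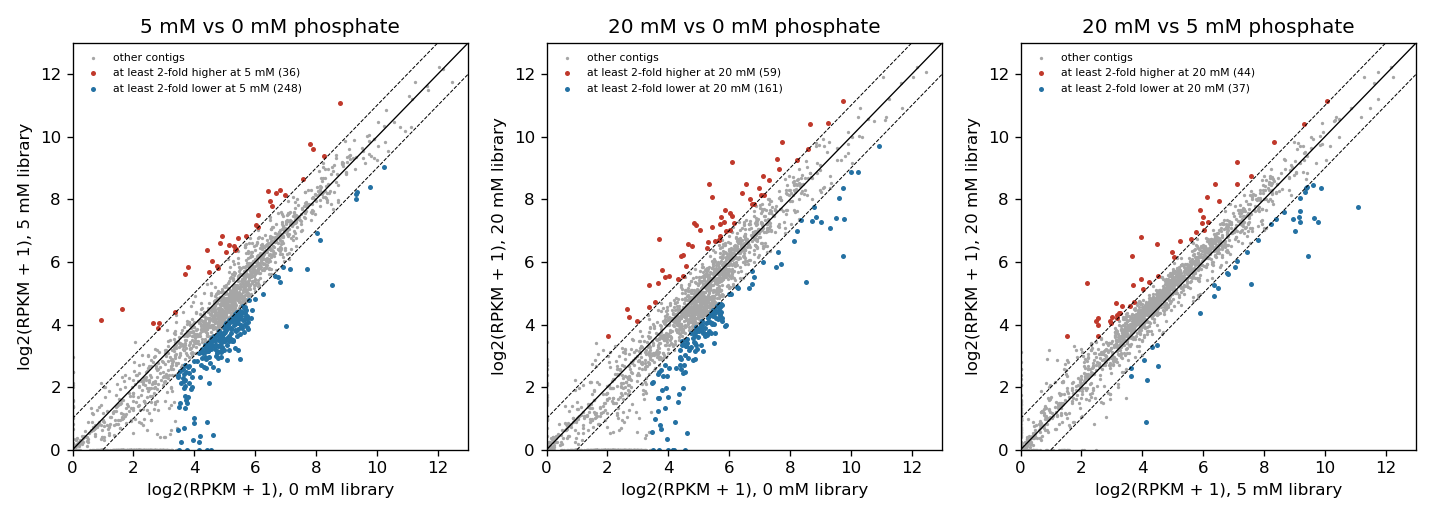
Expression of the 2047 contigs in each pair of libraries, as log2(RPKM + 1) at the lower phosphate level (x axis) and the higher level (y axis). Each point is 1 contig, the solid line marks equal values and the dashed lines a 2-fold difference; the lower contigs against 0 mM (248 at 5 mM, 161 at 20 mM) mostly peak below 100 RPKM, whereas the 81 called between 5 and 20 mM are scattered.

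**Figure D2:**
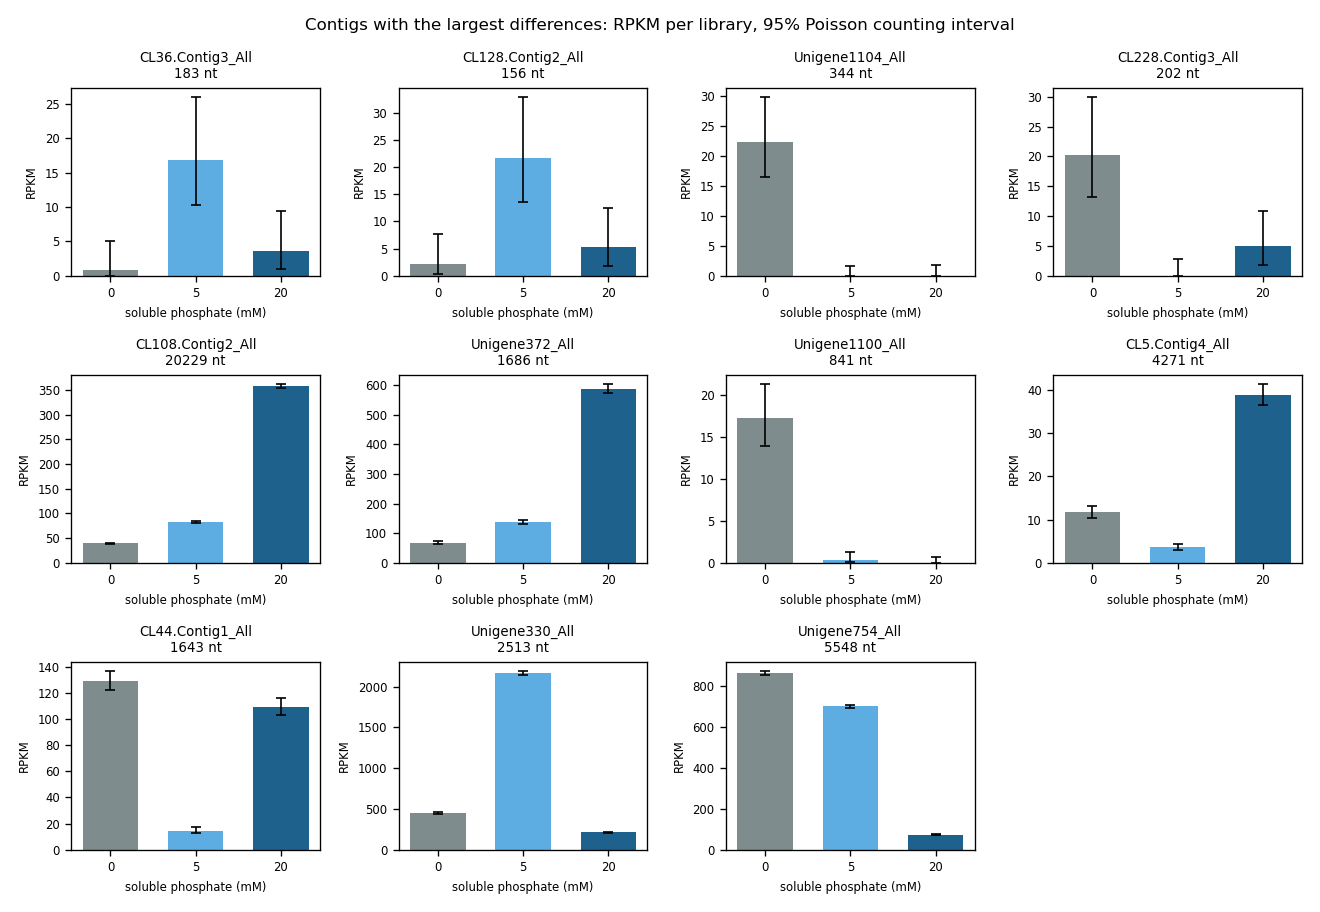
RPKM (y axis, linear, from 0) at 0, 5 and 20 mM soluble phosphate (x axis) for the 11 contigs named for their differences, with the recovered contig length in nt. Bars are single libraries and error bars are 95% Poisson intervals of the recovered reads, which cover counting error only; Unigene330_All peaks at 5 mM with 2167 RPKM and CL108.Contig2_All at 20 mM with 358 RPKM.

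The responses to 5 and 20 mM were set against each other over the 1402 contigs above the minimum in both comparisons. Lower at both levels were 123 contigs, from 248 lower at 5 mM and 161 lower at 20 mM. Higher at both levels were 22 contigs, from 33 higher at 5 mM and 56 higher at 20 mM among these 1402, and 2 contigs were called in opposite directions. Independent lists of these sizes would share 28.5 lower and 1.32 higher contigs. Since both comparisons use the same 0 mM library, overlap arises without any effect. With 3 unchanged libraries simulated 1000 times, 13.8 contigs were lower at both levels on average (95th percentile 20.05) and 13.9 were higher (95th percentile 20). The noise was the difference between 20 and 5 mM, less its median within each of 10 groups of contigs by mean level. The simulated libraries thus had no overall shift, whereas the observed counts include one. After median centring, 73 contigs were lower and 36 higher at both levels. The simulated noise is that between the 5 and 20 mM libraries and bounds nothing about the 0 mM library. That library correlated less with the others and held most of the contigs seen in 1 library alone (268, against 10 and 18). With a single 0 mM library the control could not be split, so the whole excess may come from that library.

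Across the 3 levels, 376 contigs passed the rule in at least 1 comparison. They were classed by the direction of each step alone, whatever its size. The lowest value was at 5 mM for 214 of them, or 56.9%. Only 44 contigs in all passed the rule as higher at 20 than at 5 mM. Most of the 214 therefore had no called rise between these levels. The value was lower at each step for 73 contigs, higher at each step for 46 and highest at 5 mM for 40, and the remaining 3 were tied at 1 step. The class lowest at 5 mM held 230 contigs after upper quartile scaling and 176 with equal totals. Relative to the median differences it held 78, against 84 highest at 5 mM. With a minimum of 50 RPKM it held 29, fewer than the 37 higher at each step and the 35 highest at 5 mM. Of the 305 contigs of at least 10000 nt, 37 passed the rule in 1 or more comparisons.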

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

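No comparison could be tested against replicates, so the range over settings is the main guide to how firm the counts are. No named contig changed direction under any setting that could score it, but the settings could hardly have changed it. A minimum, a threshold or a choice of contigs leaves a contig's difference as it is, and a pseudocount cannot reverse its sign. Only the scalings could do so in principle, and their shifts were small beside the named differences. Median centring at 5 against 0 mM took off a median of -0.35, while the smallest named difference was 2.82 in size. The kept directions therefore say little about how firm they are. Summing clusters left the CL contigs unscored. In size, 12 of the 152 alternative differences of named contigs moved, all with another pseudocount. With a pseudocount of 10, CL36.Contig3_All went from 3.23 to 1.30 at 5 against 0 mM and Unigene1104_All from -4.55 to -1.70. Of 122 alternative counts, 41 moved by over 1.5 times. The main counts were 284 contigs at 5 against 0 mM, 220 at 20 against 0 mM and 81 at 20 against 5 mM, with 123 lower and 22 higher against 0 mM at both levels. In that order of comparisons, they were 108, 117 and 46 with a pseudocount of 10; 588, 526 and 156 without a minimum; 57, 88 and 51 with a minimum of 50 RPKM; and 33, 37 and 14 with a 4-fold threshold. They were 165, 125 and 48 over contigs of at least 1000 nt, an alternative added after the data had been seen. Lower at both levels were 41 contigs with a pseudocount of 10, 385 without a minimum, 20 with a minimum of 50 RPKM, 18 at 4-fold, 73 after median centring, 192 after upper quartile scaling and 70 over contigs of at least 1000 nt. Higher at both levels were 0 at 4-fold, 36 after median centring, 12 with clusters summed (also added later) and 11 over contigs of at least 1000 nt. With a minimum of 50 RPKM, the share of higher contigs was 50.9% at 5 against 0 mM and 53.4% at 20 against 0 mM, so the predominance of lower contigs rests on contigs below that level. Of the dose patterns, 39 contigs were lower at each step and 72 lowest at 5 mM with a pseudocount of 10, and 19 and 29 with a minimum of 50 RPKM, where 37 were higher at each step and 35 highest at 5 mM, so lowest at 5 mM was no longer the largest class. At 4-fold, 7 were higher at each step, 18 lower at each step, 8 highest at 5 mM and 23 lowest at 5 mM. After median centring, 84 were highest and 78 lowest at 5 mM. After upper quartile scaling, 29 were higher and 128 lower at each step. Over contigs of at least 1000 nt, 28 were higher at each step, 33 lower at each step and 131 lowest at 5 mM. The minimum of 50 RPKM and the limit of 1000 nt leave fewer contigs to test, and the 4-fold threshold keeps a part of the 2-fold calls by construction. Dropping the minimum can only add contigs, and a larger pseudocount makes every difference smaller in size. Median centring and upper quartile scaling shift the contigs of a library alike, which changes the balance of directions by construction. For summed clusters the cause was not tested.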

Other observations

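The tests of contigs made from a single library's reads, of another source of RNA or DNA, of counting noise and of a single scaling factor were chosen after the result had been seen; the others were written down before. A first version of the test of a single scaling factor, written down before, asked for 40 to 60% higher contigs after median centring; both comparisons gave 40%, but centring itself evens the split, so that version decides nothing and is dropped. The comparison of clusters with shuffled directions was also added after the data had been seen. At 20 against 5 mM, 5 clusters of related contigs held 2 or more contigs past the 2-fold rule, and 0 of them held both directions. Shuffling the directions among these contigs 1000 times gave 2.79 such clusters on average, with 95% of shuffles between 1 and 4. At 20 against 0 mM, 3 of 14 clusters held both directions, against 6.33 after shuffling (4 to 8). At 5 against 0 mM, 6 of 18 did, which lies within the shuffled range of 4 to 9 around 7.06. The contigs of a cluster are not independent, so the shuffled ranges are no test.

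Some contigs had reads only in the 0 mM library, among them Unigene1104_All, the largest loss named at both 5 and 20 mM. Reads on 268 contigs were found at 0 mM alone, against 10 contigs at 5 mM alone and 18 at 20 mM alone. By the recovered minimum values, these 268 contigs were short (median 187.5 nt) and held 1518 reads. With reads in 1 library only, a divisor shared by the length and that 1 count stays hidden, so both may be understated. Of these contigs, 244 are among the 356 numbered from Unigene 1000 to 1400. Of contigs with at least 50 reads at 0 mM, 4 had at most 2 reads in each of the other libraries, among them Unigene1100_All. In the other direction, no contig with at least 50 reads at 5 or 20 mM had at most 2 reads at 0 mM (0 and 0 contigs). Depth argues against a sampling origin. With each contig at 1 level in the 3 libraries, the library totals would give 40.1 contigs seen at 0 mM alone. The same calculation gives 43.4 at 5 mM alone and 39.1 at 20 mM alone, against the 10 and 18 found. It includes the 268 contigs themselves, so these numbers are only a rough guide. Contigs assembled from a single library's own reads, if each library had been treated alike, would appear at 5 and 20 mM too, where the larger number was 18. That number is part of the pattern itself, so it is no separate test. The 268 contigs held at least 0.0249% of the reads of the 0 mM library. RNA or DNA of another source in that library cannot be told apart from transcription at 0 mM phosphate, because no sequence was used here. A different treatment of that library in the assembly is untested.

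The predominance of lower contigs at 5 and 20 mM may reflect more than library scaling. A single factor per library would shift contigs of every level alike. The median difference at 5 against 0 mM was instead -0.52 for contigs peaking at 10 to 30 RPKM and 0.13 for those at 300 RPKM or more, a gap of 0.66 with a bootstrap interval over contigs of 0.51 to 0.77. At 20 against 0 mM the gap was 0.42, with an interval of 0.25 to 0.58. At 20 against 5 mM, where the predominant direction is not settled, it was -0.17, with an interval of -0.30 to -0.04. A gap by level thus also arises between the libraries at 5 and 20 mM, in the other direction. Contigs are not independent replicates, so these intervals do not cover the spread between cultures. With equal summed RPKM, 16.4% of the called contigs were higher at 5 mM and 28.9% at 20 mM. Also leaving out the 10 contigs of highest mean RPKM gave 16.7% and 28.4%. The contigs with the most reads were not left out as a set. The contigs left out therefore do not account for the pattern. Counting noise left equality open for 2 of the 248 lower contigs at 5 mM. These contigs had been picked from the same counts, so this alone cannot exclude counting noise. In the simulation with counting error only, 7 of 1282 unchanged contigs passed the rule. The simulated lengths were drawn at random, so that number is only a guide. A broad low-level signal at 0 mM, from the cells or from elsewhere, stays open and untested.

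Some long contigs had almost no reads. Of 1068 contigs of at least 2000 nt, 26 had fewer than 10 reads in every library, and the longest of these was 17019 nt. A candidate explanation is that their reads were placed on a related contig. Of these contigs, 61.5% belonged to a cluster, against 36.8% of the other 1042 (Fisher's exact test over contigs, 2-sided, p = 0.013, odds ratio 2.75), which is consistent with it. Contigs are not independent, and 10 of the 26 were singly numbered.

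The RPKM of all 2047 contigs came out as whole reads, whereas fractional estimates would not. The recovered reads were 96.2%, 96.2% and 96.1% of the totals at 0, 5 and 20 mM, fewer than the 97.2% that came back in the simulation. Hidden divisors cost reads in that simulation; whether they account for the whole shortfall here is untested.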
